A study of Mus musculus with 24 samples.

How the data were processed

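Total RNA of C2C12 myoblasts was measured on 24 Affymetrix arrays of the type MG_U74Av2, per the headers of the array information files. The labels placed 3 arrays on each of days -2, -1, 0, 2, 4, 6, 8 and 10, counted from the addition of differentiating medium, and numbered them as replicates 1 to 3. They did not say whether replicates of a day were separate cultures, so the p-values measure only the spread between these samples. The composition of the media was not given either.

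The deposited values were intensities on a linear scale, 1 per probe set and array, as made by the authors. How the authors summarised the probes was not given in the sources used here. The mean of each array without its lowest and highest 2% of values lay between 1500.85 and 1500.98, as scaling of each array to a common target gives. The largest and smallest of these means differed by a factor of 1.00008, within the tolerance of 1.1 set for leaving the scale untouched, so no further scaling was done. Of 12488 probe sets, 66 were controls and were left out, which left 12422. Probe sets were named by the platform annotation, and 10817 symbols were brought up to date by gene identifier from a table of mouse RefSeq gene names. That gave 1 symbol for 10833 probe sets, several for 396 and none for 1193.

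Values under the 20th percentile of all values, 77, were raised to it, which placed between 15.7% and 25.6% of the values of an array at this floor. They were then converted to log2. A probe set was tested when its mean on at least 1 day was above the 40th percentile, 277.7, and 8484 passed. Of these, 7635 named 1 gene, and they covered 6287 genes. The number of arrays limits the precision of every change.

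The 8 days were fitted together in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend in the variance prior). The fit had 16 residual degrees of freedom, and the prior added 6.43. Tests were 2-sided, with Benjamini-Hochberg adjustment over all probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. A moderated F test asked whether any day differed. The main comparisons were day 0 against day -2, day 2 against day 0, day 10 against day 0 and day 10 against day 2. The other steps between successive days were counted. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

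The comparisons, the 33 gene lists, the rule for naming genes and the settings recomputed below, apart from those named as added, were chosen before the data were examined. Lists were tested with camera at a preset correlation of 0.01 between genes, with adjustment over all 132 tests (33 lists in 4 comparisons). A list needed 5 measured genes, and each gene was represented by the probe set with the highest mean log2 value among those naming only that gene. Of the 132 tests, 74 passed at the preset correlation, 49 upward and 25 downward. With a correlation estimated from the arrays 57 of the 74 held: 19 of 21 between day -2 and day 0, 15 of 20 between day 0 and day 2, 15 of 18 between day 0 and day 10 and 8 of 15 between day 2 and day 10. The mean, the median and the test differed in sign for 0 of the 74 and for 18 of the other 58. Counts of members were also made with p-values adjusted over the list alone.

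Named for each main comparison were the 5 genes with the largest rise and the 5 with the largest fall among called probe sets naming 1 gene, and up to 4 called members of each list with the largest changes. Whatever their result, Myod1, Myf5, Myog, Mef2c, Myh3, Acta1, Tnnt3, Ckm, Des, Chrna1, Cdkn1a, Ccnd1, Ccnb1, Mcm5, Id1, Id3, Igf2 and Col1a1 were named too, but no probe set named Ccnb1 alone. For a step with 5 or fewer calls all were named. Probe sets without a single symbol were counted only. A gene with all 3 arrays of a day at the floor was given a lower bound, and so, by a choice made later, was a gene with 2 of 3. Of 1147 genes with several probe sets, 4, 2, 1 and 1 had probe sets called in opposite directions in the 4 main comparisons in the order above.

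The array information files gave 5 chip lots and 11 scan days. The largest lot held 10 arrays and 2 lots held 1 array each, 7 scan days held arrays of more than 1 day and none held more than 4 arrays. Within the lots and scan days that held both days of a comparison, the changes were set against those of the remaining arrays, for probe sets called without the arrays of the 2 days in the batch and where at least 10 were called. Between 93.5% and 98.3% of them changed in the same direction, and slopes of the within-batch changes on the others lay between 0.717 and 0.895. No scan day held both days of day 0 against day -2, day 10 against day 0 or day 10 against day 2. These comparisons were therefore checked within chip lots only. The scan-day values came from 1 array of each day.

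Each result was recomputed, with 1 choice changed at a time, under quantile normalization, floors at the 5th and 40th percentiles, a pseudocount in place of the floor, no filter on dim probe sets, a stricter filter (60th percentile), a variance prior without the trend, a robust prior, the replicate number as a block, and chip lot or scan day as a fixed factor. Further ones were a fit of the 6 arrays of a comparison alone, leaving out each array, the estimated correlation, the mean of all probe sets of a gene, and an adjusted p under 0.01. Under the scan-day factor, replicates 1 and 2 of day 0, each alone on its scan day, carried no information. Day 0 then rested on its replicate 3, scanned on the same day as replicate 1 of day 2. The counts, given for each main comparison, of calls that this factor ended left out genes named there on more than 1 probe set. Chip lot and scan day as random blocks, and a fit of the largest chip lot alone, were added after seeing the data. That fit had 3 residual degrees of freedom, from days 0, 2 and 6 with 2 arrays each, and the lone arrays of days -2, -1, 8 and 10 were assumed to vary like these.

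The procedure was tested on simulated data with the spread of these arrays and known changes in 67 probe sets at 1.5-fold, 67 at 2-fold and 66 at 4-fold among 8484. It recovered 44.8%, 64.2% and 86.4% of them for day 0 against day -2, where 4.41% of the calls were false. For day 2 against day 0 these values were 41.8%, 65.7%, 83.3% and 8.63%, for day 10 against day 0 46.3%, 68.7%, 84.8% and 6.34%, and for day 10 against day 2 32.8%, 52.2%, 84.8% and 5.83%. In the other 6 steps between 50.7% and 67.2% of the 2-fold changes were recovered, and for the F test over all days 61.2%. A simulated list of 30 genes shifted by 0.5 had an adjusted p of 4.62e-27, and of 200 lists without a shift 6 had an unadjusted p under 0.05 and 0 an adjusted one. Probe sets were simulated independently of each other, so the simulated lists could not test the preset correlation. Fewer probe sets changed in the simulation than were called in the data, so the recovered shares hold for that setting only.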

Results

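C2C12 is a mouse myoblast line whose cells leave the cell cycle and fuse into multinucleated myotubes when they differentiate. Total RNA from C2C12 cultures was measured on 24 Affymetrix oligonucleotide arrays of 1 design, 3 arrays on each of 8 days. Cells on days -2 and -1 were proliferating, cells on day 0 were confluent and received the differentiating medium, and the remaining arrays held cells kept in that medium for 2, 4, 6, 8 or 10 days. The labels did not say whether the RNA of day 0 was taken before or after the medium was added. The question the days pose is which genes changed before and during differentiation, and when. Of 12422 probe sets that were not controls, 8484 were bright enough on at least 1 day to be tested, and 7635 of them named 1 gene, covering 6287 genes. Changes are differences of mean log2 intensity ± standard error with n = 3 arrays on each day. Adjusted p-values come from limma with Benjamini-Hochberg adjustment. A probe set or list was called when its adjusted p was under 0.05, and gene lists were tested with camera. "At least" marks a change between 2 days on the lower of which 2 or 3 of the 3 arrays lay at the floor of the signal scale. Arrays of a day at the floor show no spread between them. They therefore lower the standard error and the p-value of such a gene in every comparison, because the fit pooled the spread over all days. Genes with 2 arrays or 1 array at the floor on the lower day are given after each comparison.

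Arrays of the same day correlated at 0.958 on average over the tested probe sets, from 0.935 to 0.974, and arrays of different days at 0.898. The first principal component held 46.9% of the variance and placed the arrays from -66.5 on day -2 to 36.5 on day 8. The next component held 8.34% and set day 0 apart, with its 3 arrays between 37.4 and 39.3 and the other arrays between -15.8 and 4.25. The ratio of 3' to 5' signal, a measure of RNA integrity, lay between 0.764 and 0.954 for Gapdh and between 1.01 and 1.17 for beta-actin. By day, the Gapdh ratio was highest on day -2, at 0.884 ± 0.063 (SD, n = 3). It was 0.823 ± 0.029 on day 0, 0.820 ± 0.034 on day 2 and 0.827 ± 0.043 on day 10.

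Over the whole time course, 4675 probe sets (55.1% of those tested) differed among the 8 days. Of these, 2766 changed over a range of at least 2-fold between their highest and lowest day and 849 over at least 4-fold. Myog, the transcription factor myogenin that commits myoblasts to differentiation, stood at 8.69 ± 0.38 log2 units (SD, n = 3) on day -2, 14.24 ± 0.51 on day 0 and 14.67 ± 0.08 on day 2. Myh3, the embryonic myosin heavy chain, was at the floor on all arrays of days -2 and -1, at 8.84 ± 0.11 on day 0 and at 13.94 ± 0.06 on day 2. Id3, an inhibitor of myogenic helix-loop-helix factors, moved the other way between those last days, from 14.02 ± 0.09 to 9.79 ± 0.16. Col1a1, which encodes a chain of type I collagen, stood at 11.01 ± 0.17 on day -1 and at 14.14 ± 0.39 on day 10. The highest daily mean fell on day -2 for 1220 of the 4675 probe sets, on day -1 for 667, on day 0 for 734 and on day 2 for 267. It fell on day 4 for 464 probe sets, on day 6 for 249, on day 8 for 543 and on day 10 for 531. A fit with scan day as a fixed factor left 2529 probe sets that differed among the days, and 1 with scan day as a random block left 4664.

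**Figure D1:**
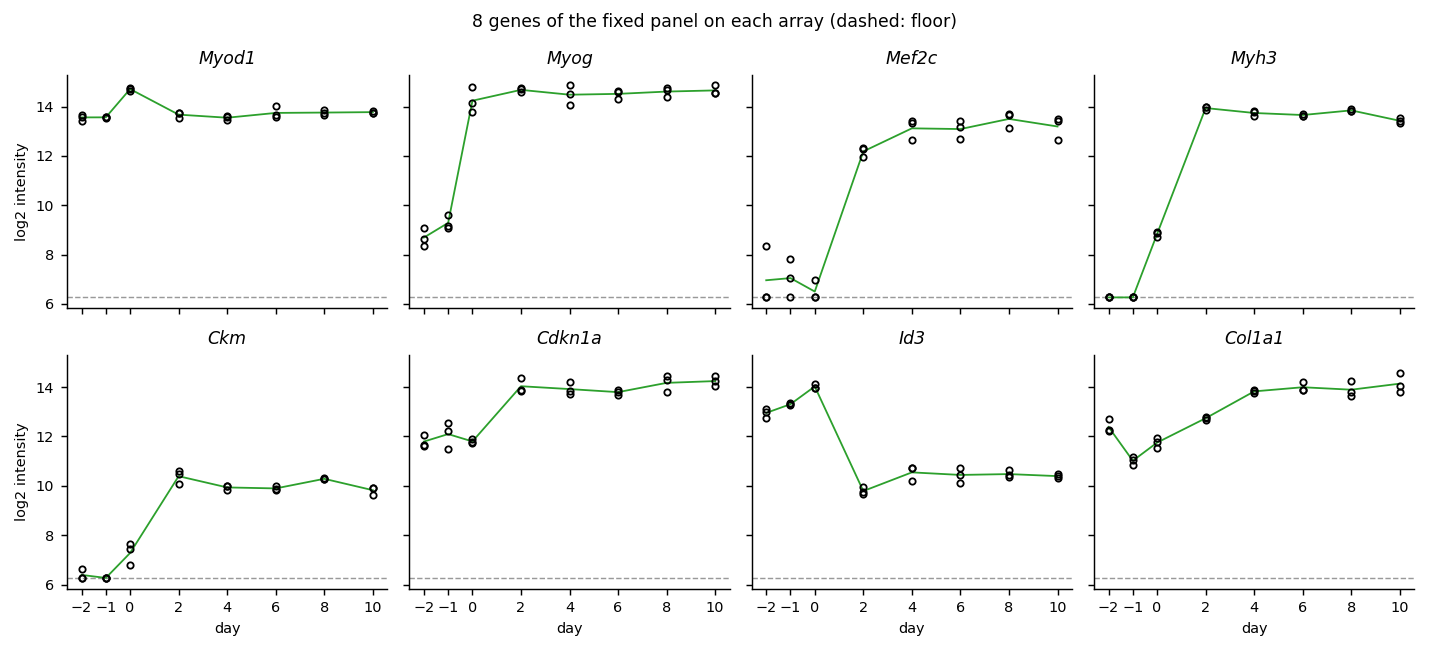
Log2 intensity of 8 genes (vertical axis) against culture day (horizontal axis), with 1 circle per array, a line through the means of 3 arrays and a dashed line at the floor. Myog stood at 8.69 ± 0.38 (SD) on day -2 and 14.24 ± 0.51 on day 0, while Myh3 stood at 8.84 ± 0.11 on day 0 and 13.94 ± 0.06 on day 2.

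The comparison of day 0 with day -2 asked what differed between proliferating cells and confluent cells on the day of the medium change. Genes of contraction rose and genes of cell division fell from day -2 to day 0. Tnnt1, slow skeletal troponin T, rose by 7.03 ± 0.18 on the log2 scale (probe set 161361_s_at), Actc1, cardiac alpha-actin, by 6.62 ± 0.17 (101028_i_at), and Myog by 5.54 ± 0.22 (103053_at). The proteoglycan Ogn (6.63 ± 0.36), the secreted protein C1qtnf3 (5.89 ± 0.13) and Mgp (5.55 ± 0.16), a matrix protein that inhibits calcification, were the remaining largest rises. The largest falls were those of Kifc1, a mitotic kinesin (-3.70 ± 0.30, 98471_f_at), Gzmd (-3.44 ± 0.50), Sprr1a (-3.40 ± 0.33), Ccnb1ip1 (-3.20 ± 0.48, a fall of at least that size) and the histone chaperone Asf1b (-3.15 ± 0.21).

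Of the mitosis and G2/M genes, 47 of 48 measured fell and none rose (47 fell when adjusted over the list alone), with a mean change of -1.61 (adjusted p = 2.07e-32). Examples were Ect2 (-2.84 ± 0.32), Top2a (-2.48 ± 0.19), Kif20a (-2.35 ± 0.16) and Aurka (-2.32 ± 0.18), which act in cytokinesis, chromosome untangling and spindle assembly. DNA replication and S phase genes fell in 41 of 46 cases (42 adjusted over the list alone; mean -1.56, adjusted p = 8.37e-24). Among them were Hells (-3.15 ± 0.29), Tk1 (-2.70 ± 0.14) and Nasp (-2.56 ± 0.33), as well as Mcm5 (-1.81 ± 0.18), a subunit of the replicative helicase. Ccnd1, the G1 cyclin D1, fell by 1.39 ± 0.20. Cdkn1a, the cyclin-dependent kinase inhibitor p21, was at 0.01 ± 0.21 and was not called (adjusted p = 0.993). Cell cycle inhibitors and pocket proteins rose in 12 of 23 cases and fell in 4 (mean 0.46, adjusted p = 0.00293). Gas1 stood at 2.64 ± 0.12, Gadd45a at 2.07 ± 0.12 and Cdkn2d at -2.38 ± 0.32. Ribosome biogenesis genes fell in 20 of 33 cases and rose in 1 (22 fell adjusted over the list alone; mean -0.61, adjusted p = 1.14e-08). Members included Pa2g4 (-1.61 ± 0.16), Nhp2 (-1.34 ± 0.15) and Ranbp1 (-1.33 ± 0.14).

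The 6 lists of sarcomere, calcium handling, junction and membrane complex genes all rose. Developmental, slow and cardiac sarcomere isoforms rose in 11 of 15 cases (mean 1.77, adjusted p = 5.19e-10). On the probe set that represented each gene in the list, Tnni1 (3.40 ± 0.13), Tnnc1 (2.81 ± 0.15) and Mybph (2.72 ± 0.15) were among the largest changes. Myh3 rose by at least 2.57 ± 0.09. Fast skeletal isoforms rose in 9 of 12 cases (mean 1.96, adjusted p = 6.32e-11). Myl1 stood at 5.08 ± 0.15, Acta1, skeletal alpha-actin, at 3.02 ± 0.14 and Tnnt3, fast troponin T, at 2.79 ± 0.18. Sarcomere scaffold genes rose in 7 of 11 cases and fell in 1 (adjusted p = 6.70e-04), and excitation-contraction coupling genes rose in 8 of 14 (adjusted p = 1.45e-04). Neuromuscular junction genes rose in 9 of 14 (adjusted p = 5.67e-05) and dystrophin-glycoprotein complex genes in 6 of 10 (adjusted p = 3.15e-04). Examples were Pdlim3 (2.99 ± 0.17), Atp2a1 (2.82 ± 0.22), Chrng (3.43 ± 0.33) and Sgca (at least 3.71 ± 0.24), and Chrna1, the acetylcholine receptor alpha subunit, rose by 1.08 ± 0.09. Des, the intermediate filament desmin, rose by 0.61 ± 0.16 and Ckm, muscle creatine kinase, by at least 0.89 ± 0.22. Myogenic transcription factors rose in 9 of 17 cases and fell in 1 (mean 0.73, adjusted p = 0.00410). Smyd1 rose by at least 2.53 ± 0.16, Mef2a by 1.29 ± 0.11 and Myod1, the factor that specifies myoblasts, by 1.15 ± 0.10. Myf5, another such factor, was at -1.19 ± 0.27. Mef2c, with 2 of 3 arrays of each day at the floor, was at -0.46 ± 0.42 and was not called (adjusted p = 0.486).

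Antagonists of these factors rose as well, in 8 of 14 cases with no falls (mean 0.62, adjusted p = 5.44e-04), including Snai1 (1.39 ± 0.20), Id1 (1.24 ± 0.13) and Id3 (1.07 ± 0.15). Among secreted and signalling genes, the insulin-like growth factor list rose in 9 of 18 cases (adjusted p = 5.49e-04). The growth factor Igf2 stood at 4.99 ± 0.22, Mest at 2.61 ± 0.27 and Peg3 at 1.84 ± 0.19. TGF-beta, BMP and myostatin genes rose in 15 of 29 cases and fell in 1 (adjusted p = 9.12e-05; Tgfb1 (2.47 ± 0.19) and Fst (2.04 ± 0.17)). Extracellular matrix genes rose in 23 of 52 and fell in 4 (adjusted p = 1.24e-05; Col6a1 (2.72 ± 0.17) and Dcn (2.53 ± 0.34)). Col1a1 was at -0.63 ± 0.17, called with all arrays and not without replicate 2 of day -2 (-0.47, adjusted p = 0.0554). Lysosome and endosome genes rose in 17 of 29 cases and fell in 1 (adjusted p = 2.33e-06). Members included Igf2r (1.53 ± 0.15) and Ctsa (1.38 ± 0.12). Chemokine, cytokine and acute phase genes rose in 13 of 30 and fell in 4 (adjusted p = 0.0247). Members included Il1rn (3.04 ± 0.29), Ccl9 (at least 2.80 ± 0.63), Il6 (2.09 ± 0.42) and Cxcl5 (-2.60 ± 0.54).

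Ubiquitin ligase and muscle proteolysis genes fell in 17 of 29 cases and rose in 4 (mean -0.26, adjusted p = 9.59e-04, and adjusted p = 0.0702 with an estimated correlation). Psma1 stood at -1.05 ± 0.16 and Psme1 at 1.18 ± 0.17. Smooth muscle actin cytoskeleton genes rose in 8 of 23 and fell in 2 (adjusted p = 0.0138, and adjusted p = 0.20 with an estimated correlation). Lima1 stood at 2.03 ± 0.15 and Cnn1 at -1.17 ± 0.24. Of marker lists for other cell types, adipocyte genes rose in 4 of 6 cases and fell in 1 (adjusted p = 0.00938; Lpl (3.10 ± 0.40) and Cebpa (1.63 ± 0.11)). The fall was that of Pparg, an adipocyte transcription factor, at -1.02 ± 0.38 (adjusted p = 0.0447), and its call ended when any of 5 of the 6 arrays was left out (adjusted p from 0.0661 to 0.152). It also ended with the floor at the 5th percentile (adjusted p = 0.315), with a pseudocount (adjusted p = 0.0801) and with the replicate block (adjusted p = 0.0520). Osteoblast and chondrocyte genes rose in 2 of 6 (adjusted p = 0.00755; Mgp (5.55 ± 0.16) and Cd200 (2.06 ± 0.16)). The macrophage (adjusted p = 0.934), endothelial (adjusted p = 0.834) and neural (adjusted p = 0.883) lists were not called. Nor were the lists of adhesion and fusion (adjusted p = 0.225), glycolysis (adjusted p = 0.427), oxidative phosphorylation (adjusted p = 0.382), fatty acid oxidation (adjusted p = 0.0870) or growth factor and immediate early response (adjusted p = 0.770). Cytosolic ribosomal proteins (adjusted p = 0.765), interferon response (adjusted p = 0.0524) and unfolded protein response genes (adjusted p = 0.444) were not called either. Reference genes were not called as a list (adjusted p = 0.189), with 2 of 12 members called: Hprt at -0.85 ± 0.11 and Pgk1 at -0.44 ± 0.10.

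In all, 2761 probe sets were called between day -2 and day 0, 1399 higher and 1362 lower on day 0, and 585 and 466 of them changed at least 2-fold. With scan day as a fixed factor, which left 6 residual degrees of freedom, 719 were called (404 higher, 315 lower), and as a random block 2776. A fit of the largest chip lot alone gave 1744 (905 higher, 839 lower). It held 1 array of day -2, which was assumed to vary like the others, and its 3 residual degrees of freedom came from days 0, 2 and 6. Within that lot 98.2% of the 1655 probe sets called without its arrays of these days changed in the same direction, and the mitosis list changed by -1.60. On all arrays, other probe sets gave 1.66 for Tnnt1, 1.88 for Actc1 and 5.14 for Ogn. Others still were not called, at -0.35 for Ckm, -0.07 for Col1a1, -0.51 for Mcm5, 0.35 for Peg3 and 0.38 for Smyd1, while 1 of Cdkn1a was called at 0.57. The scan-day factor ended 45 of the 132 calls among genes chosen by the naming rule, including Ccl9, Ccnb1ip1, Ckm, Cnn1, Col1a1, Cxcl5, Des, Gzmd, Hprt, Id3, Il6, Lpl, Pgk1, Pparg and Psme1, and the chemokine list call (adjusted p = 0.0998). It moved Id3 to 0.56, Cxcl5 to -1.45, Lpl to 2.02, Cdkn2d to -3.99 and Myf5 to -2.10. Day 0 rested on its replicate 3 alone in the fit with that factor. In the fit of the largest lot Ckm, Des, Pgk1, Pparg and Myf5 were not called, and without the filter on dim probe sets the adipocyte (adjusted p = 0.0657) and osteoblast (adjusted p = 0.0603) lists were not. The scan-day factor moved the cell cycle inhibitor list to 0.27 (adjusted p = 0.0464).

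On day -2, 2 of 3 arrays of Ckm, Sgca and Ccl9 and 1 array of Tnnt1, Ogn, Actc1, Dcn and Il6 lay at the floor, as did 1 day 0 array of Cxcl5. With the floor at the 40th percentile Ckm was not called, Myh3 stood at 0.72, Smyd1 at 0.68, Sgca at 2.08 and Tnnt3 at 1.45. Il6 stood at 0.53, Ccl9 at 1.44, Cxcl5 at -1.70, Gzmd at -2.26 and Ccnb1ip1 at -1.35. The dystrophin-glycoprotein list then stood at 0.58, and the chemokine list was not called (adjusted p = 0.0802). With the floor at the 5th percentile Ckm stood at 1.48 and Myh3 at 4.15.

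Day 2 was compared with day 0 to find what the first 2 days in differentiating medium brought. Genes of the contractile apparatus rose further, and inhibitors of myogenic factors, cytokines and growth response genes fell. Cav3, the muscle caveolin, rose by at least 6.95 ± 0.13 (probe set 162297_s_at; 5.85 on its brighter probe set). Myl4, an embryonic and atrial myosin light chain, rose by 6.40 ± 0.15 (160487_at; 0.81 on another probe set), and Mef2c, a transcription factor of muscle genes, by at least 5.68 ± 0.42 (104590_at, with 2 of 3 day 0 arrays at the floor). Myh7, slow myosin heavy chain, rose by 5.24 ± 0.29 and Myh3 by 5.10 ± 0.09. The largest falls were those of Lpl, lipoprotein lipase (-4.33 ± 0.40), Id3 (-4.24 ± 0.15, 92614_at) and the carbonic anhydrase Car3 (-4.11 ± 0.28). They were followed by F3, the coagulation starter tissue factor (-3.73 ± 0.29), and the interleukin 1 receptor antagonist Il1rn (-3.60 ± 0.29).

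Among developmental, slow and cardiac sarcomere isoforms, 14 of 15 rose and 1 fell (mean 2.96, adjusted p = 9.36e-26), and among fast isoforms 9 of 12 rose and 1 fell (mean 2.22, adjusted p = 9.69e-14). Examples were Mybph (4.51 ± 0.15), Myh1 (4.17 ± 0.11) and Tnnc2 (3.76 ± 0.20), Tnnt3 (3.97 ± 0.18) and Acta1 (2.04 ± 0.14). Sarcomere scaffold genes rose in 8 of 11 cases (adjusted p = 6.26e-09; Myom1 by at least 3.83 ± 0.29), and excitation-contraction coupling genes rose in 10 of 14 (adjusted p = 5.89e-11; Cacna1s (3.72 ± 0.30) and Ryr1 (3.31 ± 0.20)). Neuromuscular junction genes rose in 5 of 14 (adjusted p = 0.00189; Erbb3 (3.41 ± 0.13) and Chrng (1.77 ± 0.33), Chrna1 at 0.74 ± 0.09), and dystrophin-glycoprotein genes in 6 of 10, with 1 fall (adjusted p = 2.17e-04). Genes of glycolysis, glycogen and creatine metabolism rose in 10 of 22 and fell in 2 (mean 1.05, adjusted p = 1.39e-06), with Pgam2, muscle phosphoglycerate mutase, higher by at least 4.87 ± 0.16, the oxygen carrier Mb at 3.91 ± 0.22 and Ckm at 3.11 ± 0.22 (1.17 on another probe set). Oxidative phosphorylation genes rose in 9 of 50 (mean 0.27, adjusted p = 0.00161, and adjusted p = 0.143 with an estimated correlation). The muscle isoform Cox6a2 stood at 4.64 ± 0.39.

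Antagonists of myogenic factors fell in 5 of 14 cases and rose in 2 (mean -0.77, adjusted p = 0.00274). Id1 stood at -2.88 ± 0.13, Id2 at -1.71 ± 0.16 and Snai1 at -1.12 ± 0.20. The myogenic factors themselves were not called as a list (6 of 17 rose and 2 fell, adjusted p = 0.0649). Csrp3 (4.45 ± 0.23) and Smyd1 (3.59 ± 0.16) rose with Mef2c, Nfatc1 (-2.12 ± 0.24) fell, and Myod1 fell by 1.04 ± 0.10. Myog was at 0.44 ± 0.22 (adjusted p = 0.182), Myf5 at -0.19 ± 0.27 (adjusted p = 0.720) and Des at 0.02 ± 0.16 (adjusted p = 0.953), none of them called.

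Mitosis genes were higher on day 2 than on day 0 in 26 of 48 cases with none lower (31 adjusted over the list alone; mean 0.52, adjusted p = 2.19e-08). Among them were Ect2 (1.20 ± 0.32), Anln (1.04 ± 0.19) and Smc2 (0.95 ± 0.17). Replication genes rose in 14 of 46 and fell in 2 (19 rose adjusted over the list alone; mean 0.44, adjusted p = 1.45e-04). Members included Hells (1.14 ± 0.29), Rrm1 (1.06 ± 0.22) and Dck (1.01 ± 0.14). Mcm5 rose by 0.65 ± 0.18 with all arrays and was not called without replicate 1 of day 0 (0.53, adjusted p = 0.0612). Cell cycle inhibitors rose in 11 of 23 cases and fell in 4 (adjusted p = 0.0197). Cdkn1c stood at 2.96 ± 0.25, Cdkn2d at 2.61 ± 0.32 and Cdkn1a at 2.24 ± 0.21. Ccnd1 was at -0.22 ± 0.20 and was not called (adjusted p = 0.523).

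Growth factor and immediate early genes fell in 16 of 32 cases with no rises (mean -0.57, adjusted p = 9.48e-07). Among them were Hmga2 (-2.80 ± 0.24), Plaur (-1.43 ± 0.24) and Fosl1 (-1.35 ± 0.25). Chemokine, cytokine and acute phase genes fell in 12 of 30 with no rises (17 adjusted over the list alone; mean -0.78, adjusted p = 3.19e-06). Members included Il1rn (-3.60 ± 0.29), Ccl9 (-2.45 ± 0.63) and Ptgs2 (-2.03 ± 0.16). Smooth muscle actin cytoskeleton genes fell in 11 of 23 (mean -0.28, adjusted p = 5.67e-05; Csrp1 (-1.25 ± 0.12) and Lima1 (-0.99 ± 0.15)). Ubiquitin ligase and muscle proteolysis genes rose in 13 of 29 and fell in 1 (mean 0.28, adjusted p = 2.75e-04; Capn3 (1.45 ± 0.18) and Psmc3 (0.88 ± 0.10)). The calls of 4 more lists ended with an estimated correlation. TGF-beta, BMP and myostatin genes fell in 12 of 29 cases and rose in 2 (adjusted p = 0.0163, and adjusted p = 0.108 with an estimated correlation). Extracellular matrix genes fell in 17 of 52 cases and rose in 6 (adjusted p = 0.00843, and adjusted p = 0.104 with an estimated correlation). Ribosome biogenesis genes fell in 11 of 33 cases and rose in 3 (adjusted p = 0.00454, and adjusted p = 0.0920 with an estimated correlation). Adipocyte markers fell in 2 of 6 cases and rose in 1 (adjusted p = 0.0266, and adjusted p = 0.0502 with an estimated correlation). Members of those lists included Inhba (-2.37 ± 0.23), Fst (2.38 ± 0.17), Ogn (-2.03 ± 0.13 on its brighter probe set and -2.62 on the other), Postn (2.43 ± 0.25) and Rrp1b (-1.34 ± 0.15). Col1a1 rose by 0.99 ± 0.17 and Igf2 by 1.32 ± 0.22.

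The remaining 12 lists were not called between day 0 and day 2 (adjusted p from 0.0515 to 0.927). They were adhesion and fusion, fatty acid oxidation, the insulin-like growth factor axis, lysosome, cytosolic ribosomal proteins, interferon response, unfolded protein response, and the osteoblast, macrophage, endothelial, neural and reference genes. Between day 0 and day 2, 1830 probe sets were called, 951 higher and 879 lower on day 2, with 358 and 270 changed at least 2-fold. With scan day as a fixed factor 697 were called (395 higher, 302 lower), and as a random block 1904. That factor ended 23 of the 115 calls among genes chosen by the naming rule, including Ccl9, Fosl1, Hells, Igf2, Mcm5, Plaur and Rrm1, and Cdkn2d moved to 4.07. With that factor the change rested on replicate 3 of day 0 and replicate 1 of day 2, scanned on the same day. Other probe sets were not called for Mcm5 (0.12) and Smyd1 (0.35), nor was that of Ckm given above. Within the largest chip lot, with 2 arrays of each day, 1488 probe sets were called, 98.0% of the 640 called without these 4 arrays changed in the same direction, and the mitosis list rose by 0.53. On the lower day 2 of 3 arrays of Mef2c and Pgam2 and 1 array of Csrp3, Lpl and the brighter probe set of Cav3 lay at the floor. With the floor at the 40th percentile Pgam2 stood at 3.02, Myom1 at 1.98, Hells at 0.49, Ccl9 at -1.44 and the adipocyte list at -0.53. The adipocyte call ended with the floor at the 5th percentile (adjusted p = 0.0537) and with chip lot (adjusted p = 0.0789) or scan day (adjusted p = 0.0984) as a fixed factor. It also ended with no filter, with the stricter filter, with the 6 arrays alone and with the mean of all probe sets of a gene (adjusted p from 0.0678 to 0.102).

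**Figure D2:**
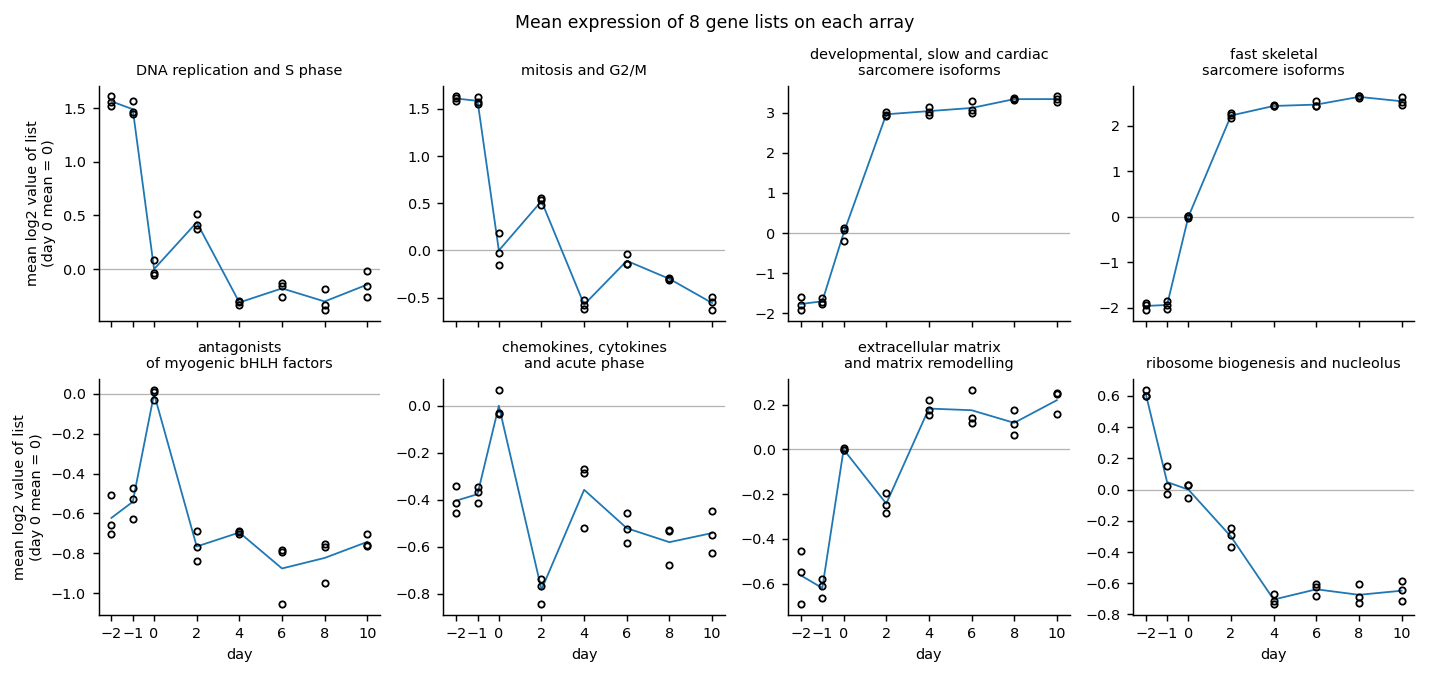
Mean log2 value of 8 gene lists (vertical axes, day 0 mean set to 0) against culture day (horizontal axes), with 1 circle per array and a line through the means of 3 arrays. The mitosis list stood at 1.61 ± 0.03 (SD) on day -2, 0.52 ± 0.03 on day 2, -0.57 ± 0.05 on day 4 and -0.11 ± 0.06 on day 6.

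The whole period in differentiating medium was covered by the comparison of day 10 with day 0. Sarcomere, calcium handling, and glycolysis and creatine genes were higher on day 10, and growth response genes, inhibitors of myogenic factors and mitosis genes were lower. The largest rises were those of Cav3 (at least 7.31 ± 0.13), Myl4 (6.75 ± 0.15; 1.05 on another probe set), Mef2c (at least 6.69 ± 0.42, with 2 of 3 day 0 arrays at the floor) and Cox6a2 (5.41 ± 0.39). Myh4, the fast IIb myosin heavy chain, rose by at least 5.63 ± 0.23 (0.48 on another probe set). F3 (-4.66 ± 0.29, a fall of at least that size), the chromatin protein Hmga2 (-4.41 ± 0.24, 99058_at), the homeobox gene Dlx2 (-4.11 ± 0.36), the glutathione transferase Gsta4 (-3.95 ± 0.42, a fall of at least that size) and the prostaglandin synthase Ptgs2 (-3.90 ± 0.16) fell the most.

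Developmental, slow and cardiac sarcomere isoforms rose in 14 of 15 cases (mean 3.34, adjusted p = 1.12e-24). Myh3 stood at 4.59 ± 0.09, Myh7 at 5.03 ± 0.29 and Mybph at 4.69 ± 0.15. Fast isoforms rose in 9 of 12 and fell in 1 (mean 2.54, adjusted p = 1.40e-12). Myh1 stood at 4.87 ± 0.11, Tnnt3 at 4.24 ± 0.18 and Acta1 at 2.08 ± 0.14. Scaffold genes rose in 8 of 11 (adjusted p = 2.06e-10; Ldb3 (3.34 ± 0.29) and Xirp1 (3.07 ± 0.15)). Excitation-contraction coupling genes rose in 11 of 14 (adjusted p = 6.32e-11; Casq1, the calcium store protein, at 4.24 ± 0.17, and Cacna1s at 3.70 ± 0.30). Neuromuscular junction genes rose in 6 of 14 (adjusted p = 1.62e-04; Ache, which breaks down acetylcholine, at 3.90 ± 0.29, and Chrna1 at 0.77 ± 0.09). Dystrophin-glycoprotein genes rose in 7 of 10 with 1 fall (adjusted p = 2.53e-05; Sgca (2.14 ± 0.24) and Dtna (1.90 ± 0.17)). Glycolysis and creatine genes rose in 13 of 22 with 1 fall (mean 1.20, adjusted p = 1.23e-07). Members included Pgam2 (at least 5.40 ± 0.16), Mb (4.22 ± 0.22) and Pygm (3.86 ± 0.23), and Ckm stood at 2.54 ± 0.22. Myogenic factors rose in 8 of 17 and fell in 3 (adjusted p = 0.0218, and 0.0572 with the mean of all probe sets of a gene). Csrp3 stood at 4.66 ± 0.23, Myf6 higher by at least 3.03 ± 0.41 and Myod1 at -0.93 ± 0.10. Myog (0.42 ± 0.22, adjusted p = 0.176), Myf5 (-0.62 ± 0.27, adjusted p = 0.0906) and Des (0.23 ± 0.16, adjusted p = 0.321) were not called.

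Antagonists of myogenic factors fell in 6 of 14 cases and rose in 2 (mean -0.74, adjusted p = 0.0155, and 0.0516 with chip lot as a fixed factor). Id3 stood at -3.63 ± 0.15, Id1 at -2.70 ± 0.13 and Twist2 at -2.36 ± 0.38. Growth factor and immediate early genes fell in 18 of 32 with no rises (mean -0.75, adjusted p = 1.39e-06). Members included Hmga2 (-4.41 ± 0.24), Plaur (-3.34 ± 0.24) and Fosl1 (-2.47 ± 0.25). Ccnd1 fell by 1.52 ± 0.20. Mitosis genes fell in 26 of 48 (35 adjusted over the list alone; mean -0.56, adjusted p = 6.66e-09). Members included Ccnb2 (-1.36 ± 0.11), Stmn1 (-1.01 ± 0.11) and Kif20a (-0.99 ± 0.16). Replication genes were not called as a list (2 of 46 fell and 1 rose, mean -0.14, adjusted p = 0.379) and Mcm5 was at -0.01 ± 0.18 (adjusted p = 0.978). Ribosome biogenesis genes fell in 20 of 33 and rose in 1 (mean -0.65, adjusted p = 6.66e-09). Members included Gar1 (-1.50 ± 0.15), Rrp1b (-1.40 ± 0.15) and Rrs1 (-1.31 ± 0.16). Smooth muscle actin cytoskeleton genes fell in 12 of 23 and rose in 1 (mean -0.41, adjusted p = 8.76e-06). Members included Csrp1 (-1.54 ± 0.12), Cnn2 (-1.43 ± 0.13) and Mylk (1.07 ± 0.21).

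Chemokine, cytokine and acute phase genes fell in 14 of 30 cases and rose in 5 (mean -0.54, adjusted p = 0.0298, and 0.108 with scan day as a fixed factor). Members included Ptgs2 (-3.90 ± 0.16), Il1rn (-2.52 ± 0.29) and Csf1 (-2.09 ± 0.15). Unfolded protein and heat shock genes fell in 13 of 29 and rose in 4 (mean -0.17, adjusted p = 0.0262, and 0.0554 without replicate 1 of day 10). The chaperones Dnajc3 (-1.05 ± 0.21) and Dnaja1 (-0.94 ± 0.16) were lower and the stress factor Ddit3 (1.41 ± 0.29) was higher. Ubiquitin ligase and muscle proteolysis genes rose in 13 of 29 and fell in 4 (adjusted p = 0.00319, and adjusted p = 0.104 with an estimated correlation; Capn3 (1.89 ± 0.18) and Psmc3 (1.01 ± 0.10)). Cell cycle inhibitors rose in 11 of 23 and fell in 5 (adjusted p = 0.0205, adjusted p = 0.0546 without replicate 3 of day 10, and adjusted p = 0.0502 with an estimated correlation). Cdkn1a stood at 2.45 ± 0.21 and Cdkn2d at 2.58 ± 0.32. Cytosolic ribosomal protein genes fell in 6 of 24 (mean -0.19, adjusted p = 0.0111, adjusted p = 0.0673 without replicate 3 of day 10, and adjusted p = 0.412 with an estimated correlation). Rpl13a stood at -0.90 ± 0.14.

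Several lists were not called between day 0 and day 10. Extracellular matrix genes went both ways (15 of 52 rose and 10 fell, adjusted p = 0.400). Among those higher were Postn (4.68 ± 0.25) and Col8a1 (2.41 ± 0.17), as well as Col1a1 (2.39 ± 0.17). TGF-beta genes went both ways as well (5 of 29 rose and 9 fell, adjusted p = 0.465). The insulin-like growth factor axis (adjusted p = 0.292) held Igfbp3 at 3.30 ± 0.30, Igfbp2 at -2.60 ± 0.13 and Igf2 at 0.69 ± 0.22. Igf2 was not called without replicate 1 of day 0 (0.53, adjusted p = 0.110) or without replicate 1 (adjusted p = 0.0551) or 3 (adjusted p = 0.0661) of day 10. The other 11 lists not called (adjusted p from 0.0509 to 0.934) were oxidative phosphorylation, fatty acid oxidation, adhesion and fusion, lysosome, interferon response, and the adipocyte, osteoblast, macrophage, endothelial, neural and reference genes.

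Between day 0 and day 10, 2391 probe sets were called, 1149 higher and 1242 lower on day 10, with 461 and 401 changed at least 2-fold. With scan day as a fixed factor 464 were called (255 higher, 209 lower), and as a random block 2413. A fit of the largest chip lot, where the lone day 10 array was assumed to vary like the others, gave 1566 (709 higher, 857 lower). The scan-day factor ended 46 of the 123 calls among genes chosen by the naming rule, including Ccnd1, Dnajc3, Fosl1, Igf2, Kif20a, Ldb3, Mylk, Psmc3, Rpl13a and Rrs1. It moved Kif20a to -0.51, Mylk to 0.59, Ldb3 to 2.06, Ddit3 to 2.66, Cdkn2d to 4.14 and the mitosis list to -0.28 (adjusted p = 0.0107). Within that lot, with 1 array of day 10, 96.2% of the 1328 probe sets called without its arrays of these days changed in the same direction, and the mitosis list changed by -0.65. The scan-day factor moved the cell cycle inhibitor list to 0.56, and day 0 rested on its replicate 3 alone in that fit. Chip lot as a fixed factor ended the calls of Igf2 (adjusted p = 0.138) and of the cytosolic ribosomal protein (adjusted p = 0.0773), chemokine (adjusted p = 0.0913) and unfolded protein lists (adjusted p = 0.0530). The chemokine call also ended with no filter (adjusted p = 0.0764) and with the stricter filter (adjusted p = 0.0797). Other probe sets were not called for Ckm (0.84), Ccnd1 (-0.98) and Dnajc3 (-0.20 and -0.61), and 1 gave -0.44 for Kif20a. Within the largest lot Igf2 was not called and Rpl13a stood at -0.57. On the lower day 2 of 3 arrays of Mef2c, Pgam2 and F3 and 1 array of Csrp3, Igfbp3 and Dlx2 lay at the floor. With the floor at the 40th percentile Pgam2 stood at 3.55, F3 at -2.94, Gsta4 at -2.09, Igfbp3 at 1.69 and Myf6 at 1.18.

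To separate later changes from the first 2 days in the medium, day 10 was compared with day 2. Cell division genes fell again and matrix and lysosome genes rose. Igfbp4, a binding protein of insulin-like growth factors, rose by 4.10 ± 0.36 (probe set 101571_g_at; 1.37 on its brighter probe set), and the tetraspanin Tspan8 by at least 3.48 ± 0.31. Ache rose by 3.47 ± 0.29, the calmodulin-dependent kinase Camk2b by 3.44 ± 0.54 and Ms4a4d by at least 3.30 ± 0.33. The largest falls were those of the water channel Aqp1 (-2.91 ± 0.23, a fall of at least that size; -0.50 on another probe set), Foxm1, a transcription factor of mitotic genes (-2.32 ± 0.61), Traf5 (-2.22 ± 0.50), the spindle protein Dlgap5 (-2.09 ± 0.33) and Cdc25c, a phosphatase that starts mitosis (-2.04 ± 0.35). Without replicate 2 of day 10, Foxm1 stood at -1.58 and was not called (adjusted p = 0.102).

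Mitosis genes fell in 44 of 48 cases (46 adjusted over the list alone) with none higher, by a mean of -1.08 (adjusted p = 1.41e-39). Among them were Kif20a (-1.91 ± 0.16), Plk4 (-1.86 ± 0.25) and Ect2 (-1.85 ± 0.32). Replication genes fell in 18 of 46 (23 adjusted over the list alone; mean -0.58, adjusted p = 2.06e-10). Pola1, a DNA polymerase subunit, stood at -1.08 ± 0.23. Mcm5 was at -0.66 ± 0.18, not called without replicate 3 of day 2 (-0.61, adjusted p = 0.0551). Ccnd1 fell by 1.30 ± 0.20, Cdkn1a was at 0.21 ± 0.21 (adjusted p = 0.612), and cell cycle inhibitors were not called as a list (adjusted p = 0.687). Ribosome biogenesis genes fell in 14 of 33 with no rises (mean -0.35, adjusted p = 1.30e-06; Ranbp1 (-0.93 ± 0.14) and Npm1 (-0.67 ± 0.11)). Unfolded protein and heat shock genes fell in 9 of 29 and rose in 1 (mean -0.18, adjusted p = 0.0135; Hspe1 (-0.75 ± 0.11) and Hsph1 (-0.61 ± 0.10)).

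Extracellular matrix genes rose in 25 of 52 cases and fell in 5 (27 rose adjusted over the list alone; mean 0.46, adjusted p = 1.13e-08). The proteoglycan Dcn stood at 2.78 ± 0.34, Mfap5 at 2.89 ± 0.30 (0.39 on another probe set), Postn at 2.24 ± 0.25 and Col1a1 at 1.40 ± 0.17. Lysosome genes rose in 9 of 29 with no falls (mean 0.31, adjusted p = 1.39e-06). Members included the hydrolases Ctsd (1.28 ± 0.17), Ctsb (0.98 ± 0.08) and Hexa (0.92 ± 0.11). Sarcomere scaffold genes rose in 3 of 11 (mean 0.38, adjusted p = 0.00310; Hspb2 (0.49 ± 0.12)). Fast isoforms rose in 3 of 12 (mean 0.31, adjusted p = 0.0159, and 0.0664 without replicate 2 of day 10). Myh4 stood at 1.61 ± 0.23 and Myh1 at 0.70 ± 0.11, while Myh3 fell by 0.52 ± 0.09. Id3 was higher by 0.60 ± 0.15.

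The calls of 7 lists ended with an estimated correlation. Developmental sarcomere isoforms rose in 3 of 15 and fell in 1 (adjusted p = 0.0486, and adjusted p = 0.341 with an estimated correlation; Myl2 (1.24 ± 0.24)). Excitation-contraction coupling genes rose in 2 of 14 (adjusted p = 0.0487, and adjusted p = 0.260 with an estimated correlation; Casq1 (2.08 ± 0.17)). Fatty acid genes rose in 3 of 19 (adjusted p = 0.0223, and adjusted p = 0.0660 with an estimated correlation; Slc27a1 (1.68 ± 0.17)). TGF-beta genes rose in 5 of 29 and fell in 1 (adjusted p = 0.0487, and adjusted p = 0.182 with an estimated correlation; Inhbb (1.00 ± 0.19) and Fstl1 (0.97 ± 0.12)). Interferon response genes rose in 3 of 23 (adjusted p = 0.0335, and adjusted p = 0.108 with an estimated correlation; H2-D1 (0.83 ± 0.11)). Chemokine genes rose in 7 of 30 and fell in 3 (adjusted p = 0.0470, and adjusted p = 0.0542 with an estimated correlation; Osmr (1.46 ± 0.22) and Ptgs2 (-1.86 ± 0.16)). Smooth muscle actin cytoskeleton genes fell in 6 of 23 (adjusted p = 0.0230, and adjusted p = 0.238 with an estimated correlation; Cnn2 (-0.71 ± 0.13)). Each of these 7 calls also ended when 1 array was left out. Replicate 1 of day 2 or 2 of day 10 ended that of the developmental isoforms (adjusted p from 0.120 to 0.148) and that of excitation-contraction coupling (0.0807 to 0.0861), and replicate 3 of day 10 that of the fatty acid genes (0.103). Any array but replicate 2 of day 10 ended the TGF-beta call (0.0508 to 0.0745). Replicate 3 of day 2 or 1 or 3 of day 10 ended the interferon (0.0605 to 0.0749), chemokine (0.0539 to 0.0695, here also replicate 2 of day 10) and smooth muscle calls (0.0626 to 0.124).

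The remaining 17 lists and the cell cycle inhibitors were not called between day 2 and day 10. They were the myogenic factors and their antagonists (both adjusted p = 0.382), and 15 others (adjusted p from 0.0524 to 0.980). These 15 were neuromuscular junction, dystrophin-glycoprotein complex, adhesion and fusion, glycolysis, oxidative phosphorylation, growth factor response, insulin-like growth factor axis, ubiquitin ligases, cytosolic ribosomal proteins, and the adipocyte, osteoblast, macrophage, endothelial, neural and reference genes. Myf6, a late myogenic factor, was higher by at least 3.03 ± 0.41. Nor were Myod1 (0.10 ± 0.10), Myf5 (-0.43 ± 0.27), Myog (-0.02 ± 0.22), Mef2c (1.01 ± 0.42) or Acta1 (0.04 ± 0.14) called. Tnnt3 (0.27 ± 0.18), Ckm (-0.57 ± 0.22), Des (0.21 ± 0.16), Chrna1 (0.04 ± 0.09), Id1 (0.19 ± 0.13) and Igf2 (-0.63 ± 0.22) were not called either, and the adjusted p-values of these 11 genes lay between 0.0547 and 0.973. From the macrophage list, Cd53 was called at 2.05 ± 0.36.

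Between day 2 and day 10, 1169 probe sets were called, 553 higher and 616 lower on day 10, with 172 and 134 changed at least 2-fold. With scan day as a fixed factor 298 were called (155 higher, 143 lower), as a random block 1151, and with the 6 arrays of these days alone 779. A fit of the largest chip lot, again with a lone day 10 array assumed to vary like the others, gave 511 (203 higher, 308 lower). The scan-day factor ended 68 of the 108 calls among genes chosen by the naming rule, including Ccnd1, Cd53, Cdc25c, Cnn2, Foxm1, Hspb2, Hspe1, Id3, Inhbb, Mcm5, Myh1, Myh3, Myl2, Pola1 and Traf5. It also ended the list calls of the fast isoforms (adjusted p = 0.0560), developmental isoforms (adjusted p = 0.937), excitation-contraction coupling (adjusted p = 0.467) and TGF-beta genes (adjusted p = 0.0795). Dlgap5 (-1.10) and Myh4 (1.17) were not called within the largest lot. Within that lot, with 1 array of day 10, 96.7% of the 276 probe sets called without its arrays of these days changed in the same direction, and the mitosis list changed by -1.18. Id3, Inhbb, Mcm5, Myh3, Myl2 and Pola1 were not called there either, Foxm1 stood at -3.78 and Hspb2 at 0.83. The scan-day factor moved the sarcomere scaffold list to 0.19 (adjusted p = 0.0327). Chip lot as a fixed factor ended the calls of Mcm5 (adjusted p = 0.0643) and of the TGF-beta (adjusted p = 0.0760), smooth muscle (adjusted p = 0.108) and interferon lists (adjusted p = 0.0823). Of the 7 list calls that ended with an estimated correlation, the mean of all probe sets of a gene ended 5 (adjusted p from 0.0515 to 0.133), all but the chemokine and smooth muscle calls. No filter ended 4 (TGF-beta, developmental, excitation-contraction coupling and interferon, adjusted p from 0.0576 to 0.0639) and the 6 arrays alone 4 (TGF-beta, excitation-contraction coupling, fatty acid and smooth muscle, adjusted p from 0.0593 to 0.0750). Quantile normalization ended the TGF-beta, chemokine and smooth muscle calls (adjusted p from 0.0515 to 0.171) and the stricter filter the developmental and chemokine calls (adjusted p from 0.0644 to 0.0921). The chemokine call ended with the replicate block (adjusted p = 0.0505) and the excitation-contraction coupling call without the trend (adjusted p = 0.0645). Other probe sets gave -0.88 for Foxm1 and -0.70 for Cdc25c, and 3 of Mef2c were called (0.82, 1.06 and 1.09), as was 1 of Cdkn1a (0.44). Not called were other probe sets of Ccnd1 (-0.91), Ctsb (0.50), H2-D1 (0.29 and 0.21), Hspb2 (0.52), Mcm5 (0.51) and Myh4 (0.18).

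On the lower day 2 of 3 arrays of Ms4a4d and Aqp1 and 1 array of Igfbp4, Foxm1 and Cdc25c lay at the floor. With the floor at the 40th percentile Ms4a4d stood at 1.66, Tspan8 at 1.63, Myf6 at 1.18, Aqp1 at -1.06, Dlgap5 at -1.18 and Cdc25c at -0.83, and the chemokine list was not called (adjusted p = 0.0536). With the floor at the 5th percentile Myh1 (adjusted p = 0.190), Myh3 (adjusted p = 0.0987) and the fast isoform list (adjusted p = 0.0849) were not called. Myh3 itself lay far above the floor on day 2 (13.94) and day 10 (13.42). On days -2 and -1 all its arrays lay at the floor, with an SD of 0, which lowered the standard error pooled over all days.

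The sampled days were 1 day apart before day 0 and 2 days apart after it. Between day -2 and day -1, 788 probe sets were called (515 higher, 273 lower), and between day -1 and day 0 2189 (1011 higher, 1178 lower). Between day 0 and day 2, 1830 were called (951 higher, 879 lower), and between day 2 and day 4, 1183 (542 higher, 641 lower). From day 4 to day 6, 33 were called, 21 higher and 12 lower. Which direction held more calls depended on the setting: 30 were higher and 16 lower after quantile normalization, but 19 higher and 24 lower without the filter on dim probe sets. From day 6 to day 8 there were 4, all lower and each at adjusted p = 0.0369. They were Adss (-0.47 ± 0.08; -0.06 on another probe set, not called), an enzyme of purine synthesis, Coro1c (-0.43 ± 0.08), an actin-binding coronin, Anxa1 (-0.42 ± 0.08; -0.32 and -0.61 on others, not called), annexin A1, and 1 probe set without a single gene name (-1.52 ± 0.26). No probe set was called by limma between day 8 and day 10, where 664 had an unadjusted p under 0.05. The counts were 137, 274, 697, 502, 13, 0 and 0 for these 7 steps in order of time when scan day was a fixed factor, and 792, 2130, 1904, 1259, 54, 7 and 6 when it was a random block. Leaving out 1 array brought the count to as few as 499 from day -2 to day -1 (without replicate 1 of day -1), 760 from day 2 to day 4 (without replicate 2 of day 2), 11 from day 4 to day 6 and 0 from day 6 to day 8 (both without replicate 1 of day 6).

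**Figure D3:**
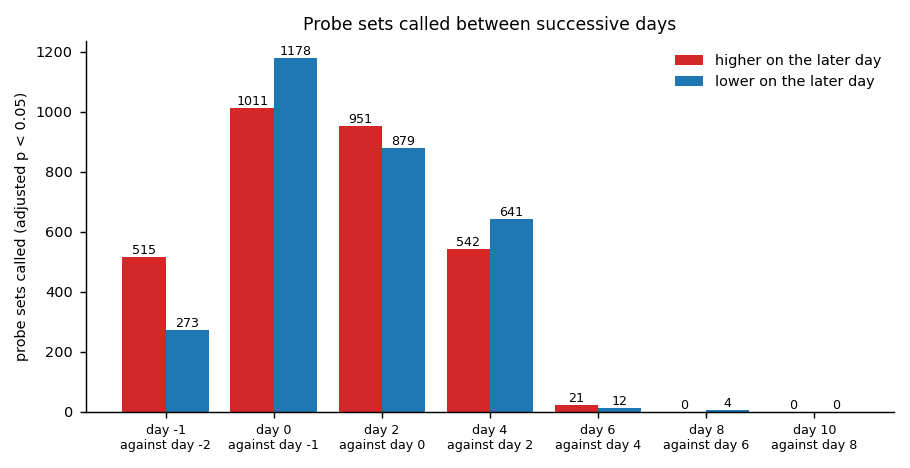
Number of probe sets called at an adjusted p under 0.05 (vertical axis, from 0) for each step between successive days (horizontal axis), split into those higher and those lower on the later day. The step from day -1 to day 0 had 1011 higher and 1178 lower, and the step from day 8 to day 10 had 0 of either.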

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

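Chip lot or scan day as a random block and the fit of the largest chip lot alone were chosen only after the result was seen, and all other settings were planned. Of 489 calls of named genes, 292 held under every setting tried for them, and so did 49 of 74 calls of gene lists. The 489 included genes named on more than 1 probe set in a comparison, which the counts given above for each main comparison left out. Counted over settings, genes kept their side of the threshold and direction in 9598 of 10238 values and lists in 1315 of 1404. Lists were not tested with the robust prior, the random blocks or within the largest lot. The size of changes in dim genes depended on the floor: Myh3 rose by at least 2.57 between day -2 and day 0 and by 0.72 with the floor at the 40th percentile.

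The count for day 6 to day 8, 4 on all arrays, was 7 after quantile normalization, 14 with the floor at the 40th percentile, 9 without a filter, 11 with the stricter filter, 0 without the trend and 7 with the robust prior. That for day 8 to day 10, 0 on all arrays, was 5, 7 and 2 for the first 3 of these. The cause was not tested. At an adjusted p under 0.01, 650 were called between day 2 and day 10. With an estimated correlation 8 of 15 lists were called there.

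With the replicate block the last steps had 1 and 1 calls. The main comparisons had 2799, 1872, 2443 and 1191 with it, and the time course 4744. Arrays of different days with the same replicate number had deviations from their day means that correlated at 0.0331 on average (-0.194 to 0.324), and 16 of 24 arrays correlated best with an array of their own number. The labels give the numbers no further meaning.

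With chip lot as a fixed factor (12 residual degrees of freedom) 18 were called from day 4 to day 6 and 4 from day 8 to day 10. With scan day as a fixed factor only 6 residual degrees of freedom remained. Day 0 was tied to the other days only through its replicate 3 and the day 2 array scanned on the same day. The main comparisons then had 719, 697, 464 and 298 calls and the steps from day -2 to day -1, to day 0, from day 2 to day 4, to day 6 and to day 8 had 137, 274, 502, 13 and 0. Over the time course 2529 were called, and the highest mean fell on day -2 for 771, on day -1 for 257, on day 0 for 332, on day 2 for 154, on day 4 for 261, on day 6 for 134, on day 8 for 298 and on day 10 for 322. Reversed with this factor and no longer called were Colq between day -2 and day 0 (-0.39, adjusted p = 0.895) and Igtp between day 0 and day 10 (-0.36, adjusted p = 0.920), and the cause was not tested. As a random block (consensus correlation 0.128) scan day gave 2776, 1904, 2413 and 1151 for the main comparisons, 4664 over the time course and 54, 7 and 6 for the 3 steps after day 4. Chip lot as a random block (0.0698) gave 2766, 1888, 2431, 1189 and 4646, and 7 from day 6 to day 8. The largest lot held 1 array of each of days -2, -1, 8 and 10, assumed to vary like those of days 0, 2 and 6, which gave the 3 residual degrees of freedom. A fit of it called 1744 between day -2 and day 0, 1566 between day 0 and day 10, 511 between day 2 and day 10, 1276 from day -1 to day 0 and 1 from day 6 to day 8. It called 67 from day -2 to day -1, with 1 array against 1.

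With the 6 arrays of a comparison alone, which leaves fewer degrees of freedom, 779 were called between day 2 and day 10, 451 from day -2 to day -1, 3 from day 4 to day 6 and 0 from day 6 to day 8. Leaving out 1 array, the count from day -2 to day -1 lay between 499 (without replicate 1 of day -1) and 677, from day 2 to day 4 between 760 (without replicate 2 of day 2) and 1042. From day 4 to day 6 it lay between 11 (without replicate 1 of day 6) and 31, with 14, 14 and 17 without replicate 3 of day 4 and replicates 2 and 3 of day 6. From day 6 to day 8 it lay between 0 (without replicate 1 of day 6) and 14 (without replicate 3 of day 8), with 2, 1 and 1 without replicates 2 and 3 of day 6 and replicate 2 of day 8. From day 8 to day 10 it lay between 0 (without replicate 1 of day 8) and 4 (without replicate 1 of day 10), with 2 and 3 without replicates 2 and 3 of day 8 and 3 and 1 without replicates 2 and 3 of day 10. When 1 replicate number was left out on every day, probe sets highest on day 2 numbered between 173 (without replicate 2) and 294 (without replicate 3). Where limma called 0 from day 6 to day 8, 651 to 855 had an unadjusted p under 0.05.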

Other observations

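The list tests of the steps between successive days, the comparisons of day 8 with day 4 and of day 10 with day 6, and the chip lot, scan day and shared array tests of the patterns below were chosen only after the result was seen, and so were the genes named here for day 4 to day 6. Of 198 list tests in 6 steps, 53 passed, and the arrays were not left out in turn for them. From day -2 to day -1, while the cells were proliferating, ribosome biogenesis genes fell in 19 of 33 cases (mean -0.57, adjusted p = 7.68e-20). Growth factor and immediate early genes fell in 12 of 32 and rose in 3 (mean -0.35, adjusted p = 1.91e-06). Cell cycle inhibitors rose in 8 of 23 (mean 0.59, adjusted p = 7.53e-09), lysosome genes in 10 of 29 (mean 0.29, adjusted p = 1.08e-04) and fatty acid genes in 8 of 19 (mean 0.30, adjusted p = 2.39e-04). From day -1 to day 0 mitosis genes fell in 46 of 48 (mean -1.59, adjusted p = 9.95e-39) and replication genes in 38 of 46 (mean -1.49, adjusted p = 6.61e-27). Each of these 7 calls held with an estimated correlation (adjusted p from 2.13e-05 to 0.0124).

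From day 2 to day 4 mitosis genes fell in 43 of 48 cases (mean -1.10, adjusted p = 2.32e-40) and replication genes in 22 of 46 (mean -0.75, adjusted p = 1.58e-16). Lysosome genes rose in 14 of 29 (mean 0.40, adjusted p = 2.22e-07), and extracellular matrix genes rose in 19 of 52 and fell in 4 (mean 0.43, adjusted p = 9.24e-06). From day 4 to day 6 mitosis genes were higher again, by a mean of 0.46 (adjusted p = 4.24e-25, and adjusted p = 4.87e-04 with an estimated correlation), with 7 of 48 called. The kinesin Kif23 rose by 1.16 ± 0.22 (n = 3) and Cdc20, an activator of anaphase, by 0.95 ± 0.14, while the metallothioneins Mt2 and Mt1 fell by 0.85 ± 0.11 and 0.70 ± 0.13, each gene with 1 tested probe set. From day 6 to day 8 the mitosis list was at -0.19 (adjusted p = 9.25e-06, and adjusted p = 0.0769 with an estimated correlation). From day 8 to day 10, where no member was called, it fell by 0.26 (adjusted p = 8.39e-09) and the replication list rose by 0.16 (adjusted p = 1.65e-04). These p-values come from camera at the preset correlation and do not measure the spread of a list mean between arrays. Relative to day 0, the replication list was at -0.30 ± 0.10 (SD, n = 3) on day 8 and -0.14 ± 0.12 on day 10. The mitosis list was at -0.30 ± 0.01 and -0.56 ± 0.07.

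On day 0, 506 probe sets naming 428 genes were called higher than on both day -2 and day 2, and 368 naming 322 genes lower. Both comparisons share the day 0 arrays, so they were also made with no day 0 array in both, in 6 ways. Then 274 to 347 probe sets were higher on day 0 in both, 3.85 to 4.45 times as many as independent lists of these sizes would share. Both fits shared the arrays of the other days, which helped to set the spread, so independent lists are only a rough yardstick. Probe sets that rose in both steps numbered 112 to 142, where independent lists would share 79.7 to 98.4. Those that fell in both numbered 23 to 40, against 60.4 to 78.2. The larger excess of probe sets higher on day 0 argues against error of single arrays as their only source. The excess was smaller for probe sets lower on day 0 in both, 153 to 220, where independent lists would share 77.8 to 90.7. The 506 included Hes1, Id1, Id2, Id3 and Snai1, 11 of 29 TGF-beta genes and 15 of 52 extracellular matrix genes, with 312 also called lower on day 10 than on day 0, and the 368 included 26 of 48 mitosis and 14 of 46 replication genes. Scaling is argued against for the 506, of which 97.6% were called in both comparisons after quantile normalization, and chip lot for 189 probe sets chosen the same way without the 4 arrays of days 0 and 2 in the largest lot, whose median change from day 0 to day 2 was -1.04 within that lot and -1.20 on the other arrays. Scan day stays open: for 1 day 0 and 1 day 2 array scanned on the same day the median was -0.86, against -0.96 on the other arrays for probe sets chosen without these 2, and 1 array a side cannot exclude it.

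The rise of the mitosis list from day 0 to day 2 (0.52 over all arrays) ran opposite to its fall in the steps before and after. Within the largest chip lot it was 0.53, against a standard deviation of 0.12 between arrays of a day, which argues against the lots. Leaving out 1 array left at least 0.45 (without replicate 3 of day 0), which argues against a single deviating array, and it was 0.50 after quantile normalization (adjusted p = 4.16e-08), which argues against scaling. With scan day as a fixed factor it was 0.71. That value rests on 1 array of each day, scanned on the same day, so scan day stays open. No biological explanation was tested.

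Few probe sets were called in the steps after day 4. The ratio of the median standard deviations of days 6 to 10 and of days -2 to 2 was 1.14. It cannot decide whether a larger spread on the later days played a part. The fit pooled the spread over all days, so a probe set had the same standard error in every step. Slow change over several days is a candidate explanation: day 10 differed from day 4 in 218 probe sets (90 higher, 128 lower), where the 3 steps between them had 37 calls added together. Day 8 against day 4 had 113 calls and day 10 against day 6 had 19.

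Each comparison of 3 with 3 arrays has 10 splits, too few for a share under 0.05. The real split and the highest of the others gave 2761 and 1 calls for day 0 against day -2, 1830 and 0 for day 2 against day 0, 2391 and 2 for day 10 against day 0, and 1169 and 0 for day 10 against day 2. For the other steps in order of time they gave 788 and 3, 2189 and 1, 1183 and 0, 33 and 2, 4 and 1, and 0 and 3. The number of splits with a count as large as the real one was 10 for the last step and 1 for each of the others. For the time course 1 of 100 regroupings, the real one, gave as many as 4675 calls, and the highest other gave 1145. That argues against a random assignment of these arrays to days. The regroupings cannot tell day from scan day or chip lot, which partly go with it.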
